A study of Mus musculus with 13 samples.

How the data were processed

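The deposited table of bead-averaged signal intensity per probe and array, with the detection p-value the authors gave beside each, was the starting point. The deposited series values are on a log2 scale, as judged from the values themselves, and share one distribution across the 13 arrays. The submitters' processing notes credit BeadStudio 3.2, RMA and lumi, without giving their role or order. The values of the MEF and ESC arrays carry more decimals than the others: 0.300% and 0.331% of them have 1 decimal, against 100% elsewhere. The values computed here correlated with the deposited ones at r = 0.978 across probes on each array.

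Signals were background-corrected by normexp with parameters fitted from the detection p-values, raised by an offset of 16, quantile-normalized and put on a log2 scale with limma 3.58.1 in R 4.3.3, with statmod 1.5.0. Of 25697 probes, 23978 had 1 gene symbol, 1719 are unnamed here, and 16 were not matched by their gene identifier. A probe was used if its detection p was under 0.01 on at least 1 of 13 arrays, which 15049 named probes met, and each gene was represented by its probe with the highest mean, leaving 10923 genes. Of these, 2914 had at least 2 detected probes.

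All arrays entered a single limma fit of 7 groups with 6 residual degrees of freedom, all from the 3 groups of 3 clones, and 3.10 prior degrees of freedom. Tests were two-sided, with the Benjamini-Hochberg adjustment over all genes tested per comparison and a threshold of 0.05. Fixed lists held 458 genes, of which 406 had a probe and 353 were tested. They were neural stem and radial glia, fibroblast and mesenchymal, pluripotency, cell cycle, astrocyte, oligodendrocyte precursor, mature oligodendrocyte, neuron, microglia and macrophage, endothelial and pericyte, ependymal and choroid plexus, interferon and MHC class I, immediate early and dissociation stress, hypoxia and glycolysis, cholesterol synthesis, forebrain, midbrain and hindbrain, Hox, imprinted, sex-linked, epithelial, and conversion factors. Each list was tested with camera in 7 comparisons, with a preset correlation of 0.01 or an estimated one, adjusted over lists and comparisons. For the in vivo pair a list's median was ranked among 10000 random lists of its size, drawn from 20 bins of mean level.

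The groups, comparisons, lists, thresholds and most alternative settings were fixed before the data were examined. Genes named are the 10 largest rises and 10 largest falls past the threshold, with groups that do not overlap, in each comparison, and the 8 largest differences each way for the in vivo pair. Up to 4 members of each list with the smallest unadjusted p, a fixed set of markers, and all sex-linked and conversion factor genes were added, and predicted genes were passed over. The NSC genes on MEF, Hba-a1 beside other arrays, Thumpd1, Brat1, Hprt and the ribosomal protein genes as a group were chosen after their values were seen.

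The pipeline was tested on simulated data of 10923 genes with 100 genes changed by log2 1 and 100 by log2 2. It recovered 89% and 100% of these for iNSC against NSC with 15 false calls, 93% and 98% for ESC NPC against NSC with 6, and 94% and 100% for iNSC against ESC NPC with 7. For iNSC against MEF it recovered 71% and 96% with 5 false calls, for ESC NPC against ESC 78% and 98% with 8, for iNSC in vivo against iNSC 71% and 96% with 5, and for NSC in vivo against NSC 66% and 95% with 9. A shifted list of 20 simulated genes gave a camera p of 3.09e-52, and 0 of 100 random lists fell under 0.05. Noise was drawn independently for each gene, with the same spread in all groups. The simulation therefore tests neither lists of correlated genes nor groups with 1 array that vary unlike the clones. In the data the cell cycle list had an estimated correlation of 0.871 in iNSC against NSC.

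Alternatives were no background correction, median scaling, the deposited values, no filter, detection on at least 3 arrays, the mean of a gene's probes, a trended robust prior, an estimated correlation, a replicate block, a fit of only the 2 groups compared, and leaving out each clone. Leaving out the in vivo arrays and keeping only genes detected on every array compared were added after seeing the data. The clone numbers of NSC and iNSC may pair, which the labels do not say. Deviations from the group mean correlated at 0.211 to 0.503 in the 3 same-numbered pairs, each above 0.1, and at -0.403 to 0.235 between other numbers. These ranges overlap, and 3 clones per group are too few to establish a pairing. Lists of iNSC against NSC were therefore also tested with the replicate block, which was added after seeing the data. A block by chip was not run, because the column names give no chip barcode.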

Results

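Gene expression was measured on Illumina mouse bead arrays in 7 kinds of sample, all labelled as strain C3H. Neural stem cells in culture (NSC), neural stem cells induced from embryonic fibroblasts (iNSC) and neural progenitors made from embryonic stem cells (ESC NPC) had 3 clones each, with 1 array per clone. The fibroblasts (MEF), the embryonic stem cells (ESC), NSC in vivo and iNSC in vivo had 1 array each. The label of iNSC in vivo gives the number 14, without a unit, for the interval since transplantation into adult brain, and the label of NSC in vivo does not mention transplantation. No cell sort is named for either.

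Of 25697 probes, the 11 arrays of cultured cells detected 40.8% to 49.9%, while NSC in vivo detected 26.7% and iNSC in vivo 26.2%. The median signal was 79.3 intensity units on NSC in vivo and 80.1 on iNSC in vivo, against 102 to 117 on the others. A gene symbol and detection on at least 1 array left 10923 genes for testing. Differences below are log2 values with the standard error from limma, and p-values are adjusted for all genes tested. Standard errors and p-values rest on a spread pooled over the 3 groups of clones. Mean variances were 0.0928 in NSC, 0.0620 in iNSC and 0.0198 in ESC NPC. On average the tight ESC NPC arrays thus lower the error used for iNSC against NSC. A group with 1 array was assumed to vary like the clones, which the data cannot check. Where no array of a group detected a gene, a lower bound of the fold is given, with each array of that group set to the higher of its lowest level among detected probes and the probe's own value. The number of arrays limits the precision.

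Across genes, iNSC and NSC arrays correlated at a mean r of 0.945, with 9 pairs between 0.934 and 0.954. Arrays within NSC reached 0.981, within iNSC 0.987 and within ESC NPC 0.996. ESC NPC stood at 0.868 from NSC and 0.850 from iNSC, and MEF at 0.807 from iNSC and 0.797 from NSC. The in vivo arrays correlated with each other at 0.918, whereas NSC in vivo and NSC gave 0.622 and iNSC in vivo and iNSC 0.603. Genes are not independent replicates, so these values carry no test.

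**Figure D1:**
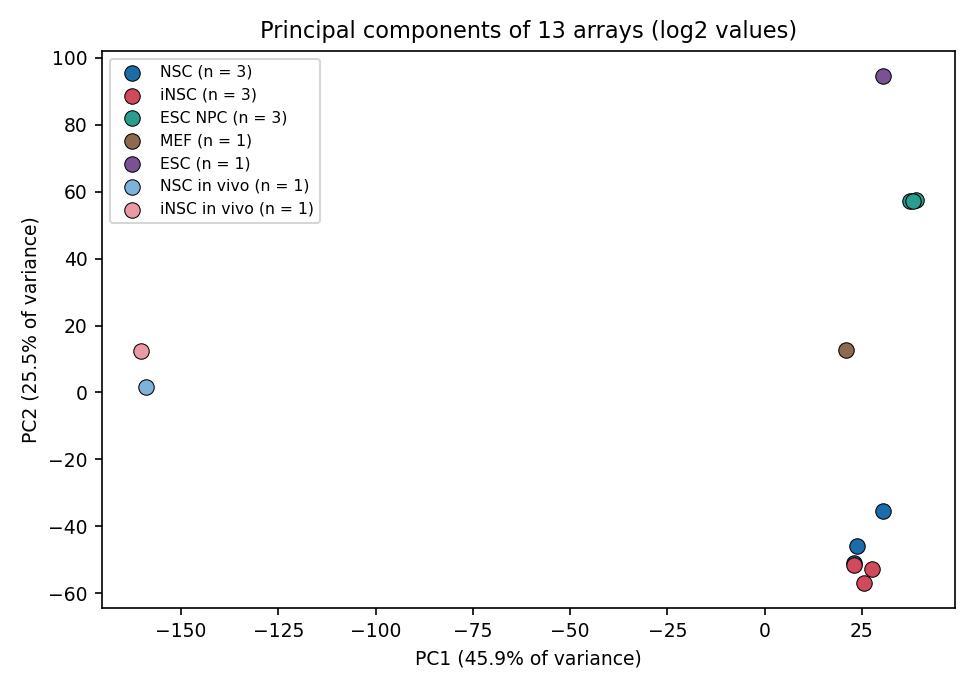
Principal components of the 13 arrays over all genes tested, with the first component (45.9% of the variance) on the horizontal axis and the second (25.5%) on the vertical axis. Each point is an array and each colour a group, and both in vivo arrays lie apart from all cultured cells.

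The comparison of iNSC with NSC asked how far cells converted from fibroblasts match neural stem cells in culture. These cells also differed in sex-linked transcripts (below), and Brat1, undetected in NSC, was at least 29.2-fold higher in iNSC. Their differences can therefore not be ascribed to the conversion alone. The Hox genes, which set positional identity along the body axis, rose as a group: 14 of 20 measured members were higher in iNSC, none was lower and 6 did not pass. Hoxa7 was higher by at least 67.7-fold (3 against 3 arrays), and Hoxa5 and Hoxc9 by at least 40.6-fold each, with adjusted p from 2.2e-09 to 7.3e-09 for these 3 genes. Adjusted over the list alone, 16 Hox genes passed, and the list shift had an adjusted p of 3.93e-17 (camera), or adjusted p = 0.00573 with an estimated correlation. The forebrain list fell in 5 of 10 genes and rose in none, among them Sp8 (at least 4.48-fold) and Dlx1 (at least 5.21-fold), transcription factors of the developing forebrain. Its adjusted p was 0.00268, and adjusted p = 0.109 with an estimated correlation. Boundary genes of midbrain and hindbrain went both ways, 2 up and 2 down of 12 (adjusted p = 0.619), with Zic1 lower by at least 24.9-fold and Irx3 at 1.81 ± 0.10 (SE).

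General stem cell genes went both ways between iNSC and NSC. In the neural stem and radial glia list 5 of 16 genes rose, 4 fell and 7 did not pass (adjusted p = 0.983). Sox2, a core factor of neural stem cells, differed by 0.00 ± 0.16 (adjusted p = 0.99), and the filament gene Nes by 0.69 ± 0.36 (adjusted p = 0.24, or 0.0047 without NSC replicate 3). Fgfr3 rose by 1.21 ± 0.12 and Olig2 by 0.53 ± 0.09, whereas Nr2e1 changed by -2.04 ± 0.22 and Sox9 by -1.47 ± 0.17. The astrocyte list rose in 9 and fell in 4 of 21 genes (adjusted p = 0.385), and the gap junction gene Gja1 changed by -7.02 ± 0.33, the largest fall under the naming rule. Gfap, an astrocyte filament, stood at 1.04 ± 0.26 with an adjusted p of 0.02, which became 0.051 without NSC replicate 2, 0.066 without iNSC replicate 1, 0.058 without iNSC replicate 2 and 0.0729 in a fit of only the 2 groups.

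Of 13 oligodendrocyte precursor genes 5 fell in iNSC and none rose (6 adjusted over the list alone), including the receptor Pdgfra at -2.78 ± 0.38 and Gpr17 at -3.69 ± 0.56. The list had an adjusted p of 0.0176, but adjusted p = 0.597 with an estimated correlation and 0.274 without NSC replicate 2. Of 19 neuron genes 7 fell and 1 rose, or 8 and 2 adjusted over the list alone, with the migration gene Dcx at -3.08 ± 0.49 (list adjusted p = 0.0175, adjusted p = 0.51 with an estimated correlation). Mature oligodendrocyte genes fell in 4 and rose in 1 of 16, where Cldn11 changed by -5.15 ± 0.36 and Cryab by 2.92 ± 0.31 (list adjusted p = 0.0725, or 0.0017 without NSC replicate 3). None of 25 cell cycle genes passed in limma, also adjusted over the list alone, with 2 at an unadjusted p under 0.05. With the clone number as a replicate block Ccne1 (-0.53, adjusted p = 0.030) and Rrm2 (-1.62, adjusted p = 0.024) passed. The list's preset test gave 0.00836, direction down. That list call ended with adjusted p = 0.757 with an estimated correlation, at 0.471 without NSC replicate 3 and at 0.229 without iNSC replicate 2. Immediate early and dissociation genes rose in 6 and fell in 1 of 20, with Gadd45g at 1.26 ± 0.18 (list adjusted p = 0.037, adjusted p = 0.559 with an estimated correlation, 0.234 without NSC replicate 2 and 0.147 without iNSC replicate 1).

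The remaining lists did not pass their test in this comparison. The fibroblast list rose in 6 and fell in 4 of 26 genes (adjusted p = 0.818), with Acta2, a smooth muscle actin, at -5.17 ± 0.39 and Twist1 higher by at least 1.67-fold. No pluripotency gene of 18 and no epithelial gene of 12 passed in limma, with 0 in each at an unadjusted p under 0.05 (list adjusted p = 0.798 and 0.769). Microglia genes fell in 1 of 20 (0.897), endothelial genes rose in 2 and fell in 1 of 18 (0.783), and ependymal genes fell in 2 of 10 (0.163), Otx2 by at least 9.36-fold. Interferon genes rose in 3 of 22 (0.73), hypoxia genes rose in 1 and fell in 1 of 16 (0.496, or 0.0017 without NSC replicate 1), cholesterol genes fell in 4 of 17 (0.235), and imprinted genes fell in 4 of 17 (0.145), Nnat by at least 53.2-fold. Of the conversion factors Pou3f4, Sox2 and Klf4, Klf4 rose by 0.79 ± 0.17 and Pou3f4 stood at -0.13 ± 0.19 (list adjusted p = 0.637). Xist, which is transcribed from the inactive X chromosome, was at least 18.0-fold lower in iNSC, while the Y-linked Eif2s3y and Kdm5d were at least 16.7-fold and 4.11-fold higher (sex-linked list, 3 up and 1 down of 4, adjusted p = 0.083).

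In all, 2150 genes changed between iNSC and NSC (limma, adjusted p under 0.05), 1121 higher and 1029 lower, and 807 of them by at least 2-fold, or 324 without background correction and 1275 with the deposited values. A fit of only these 2 groups, without the tighter ESC NPC arrays, called 1455. Further large rises were Glycam1 (5.75 ± 0.37), the retinal dehydrogenase gene Aldh1a1 (at least 18.1-fold) and Rnase1 (4.87 ± 0.59), and further large falls the matrix protease gene Mmp14 (at least 57.6-fold), Cldn10 (at least 39.5-fold) and Pla2g7 (at least 29.5-fold). Genes higher on the MEF array than in ESC NPC by at least 4-fold, 642 in all, were tested as a set because no array that defines them enters this comparison. Of these, 160 were higher and 72 lower in iNSC (camera p = 0.00546, and p = 0.148 with an estimated correlation). Thus 24.9% were higher, against 9.35% of the other genes, and 11.2% were lower, against 9.31%. The median was 0.0657. The limit also admits genes expressed in NSC, such as Egfr (9.62 on MEF, 7.15 in ESC NPC), and Hox genes, such as Hoxa5 (9.86 and 6.01). The set is therefore not particular to fibroblasts, and its rise was not separated from that of the Hox genes.

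**Figure D2:**
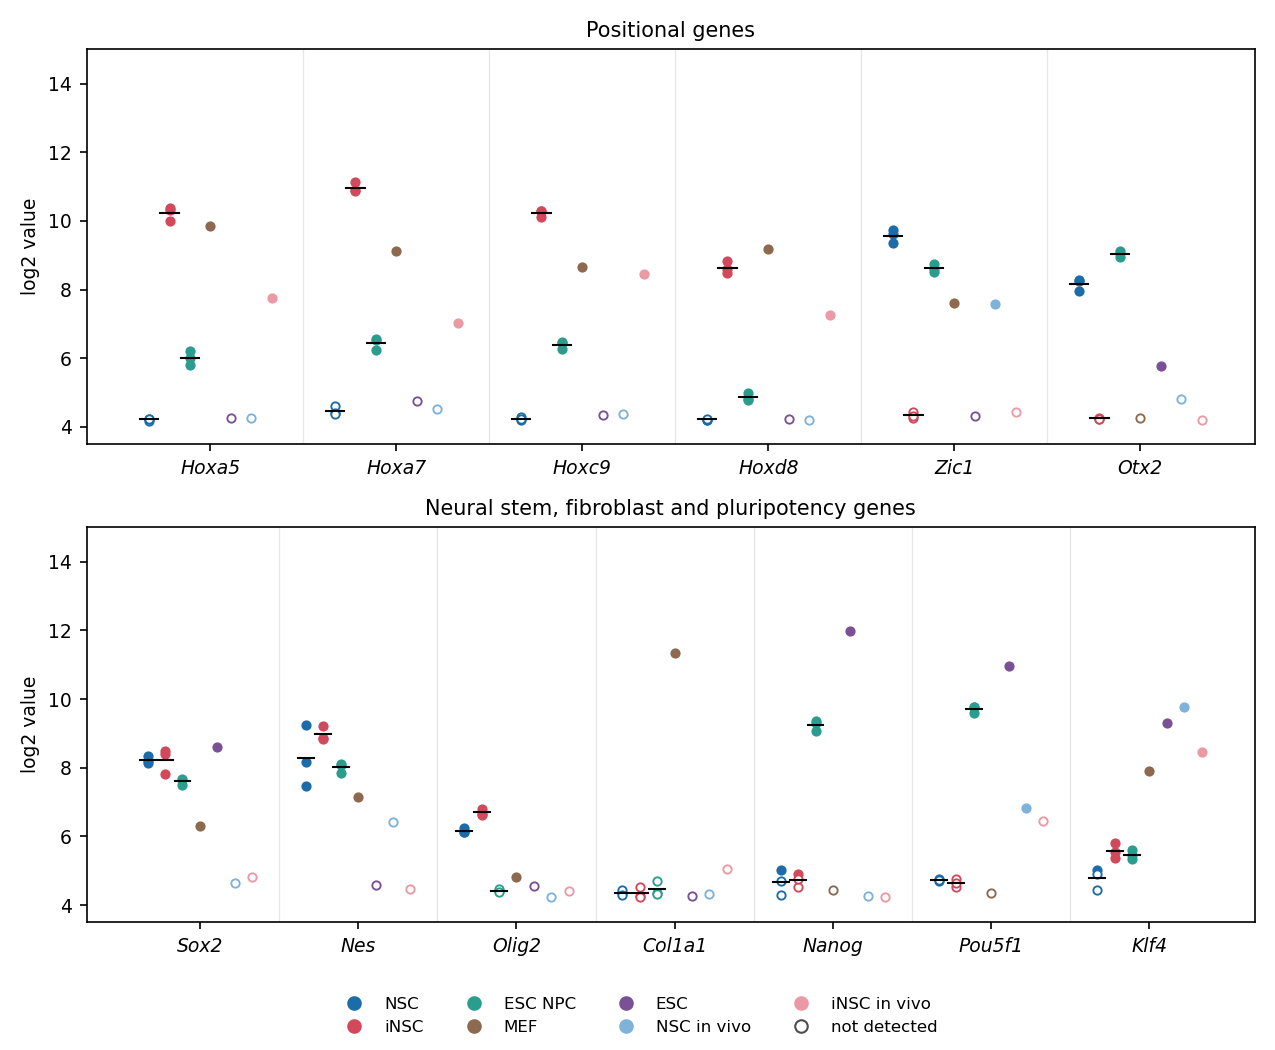
Normalized log2 level (vertical axis) of marker genes by gene (horizontal axis) and group (colour), where points are arrays, open points are arrays that did not detect the gene and short lines are means of 3 clones. Hoxc9 stood at 10.2 in iNSC, 8.64 on MEF and 4.24 in NSC, while Sox2 was 8.23 in NSC and 8.24 in iNSC.

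The next comparison set ESC NPC against NSC, asking how progenitors from embryonic stem cells differ from NSC. Pluripotency genes rose in 17 of 18 members, with none lower: Sall4 by at least 71.1-fold, Dnmt3l by at least 54.1-fold and Pou5f1, a central pluripotency factor, by at least 28.2-fold (list adjusted p = 5.41e-14, camera). Neural stem genes fell in 14 and rose in 1 of 16, with Egfr at -2.74 ± 0.14, Slc1a3 at -2.18 ± 0.14 and Sox2 at -0.63 ± 0.16 (list adjusted p = 1.7e-05). Epithelial genes rose in 10 of 12, or 11 adjusted over the list alone, such as Krt8 (at least 25-fold) and the adhesion gene Cdh1 (4.13 ± 0.11; list adjusted p = 1.59e-07). With an estimated correlation these 3 lists held, at adjusted p = 0.00573, 0.0275 and 0.0174.

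Astrocyte genes fell in 15 and rose in 2 of 21 in ESC NPC against NSC, with Apoe at -4.46 ± 0.26 and Gfap lower by at least 5.61-fold (list adjusted p = 0.000191, adjusted p = 0.123 with an estimated correlation). Oligodendrocyte precursor genes fell in 9 of 13 (0.000969, adjusted p = 0.44 with an estimated correlation), and Gpr17 was at least 65.7-fold lower. Mature oligodendrocyte genes fell in 7 of 16 (0.0563, or 0.044 without NSC replicate 2 and 0.007 without NSC replicate 3), neuron genes fell in 10 and rose in 3 of 19 (0.143), and forebrain genes fell in 5 of 10 (0.137).

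Other lists rose in ESC NPC by the preset test. Fibroblast genes were higher in 12 and lower in 2 of 26, among them the matrix gene Dcn (at least 24.5-fold) and the protease gene Mmp2 (at least 19.2-fold; adjusted p = 0.00845, adjusted p = 0.218 with an estimated correlation). Hox genes were higher in 11 of 20, Hoxc9 by at least 2.84-fold (0.000916, adjusted p = 0.0912 with an estimated correlation). Cell cycle genes rose in 13 and fell in 1 of 25 (0.00248, adjusted p = 0.74 with an estimated correlation), and cholesterol genes rose in 11 and fell in 1 of 17, or 12 and 2 adjusted over the list alone (0.00836, adjusted p = 0.495 with an estimated correlation). Endothelial genes rose in 8 of 18 (0.0336, adjusted p = 0.163 with an estimated correlation), ependymal genes rose in 6 and fell in 1 of 10 (0.0321, adjusted p = 0.173 with an estimated correlation), and midbrain and hindbrain genes rose in 7 and fell in 3 of 12 (0.0416, adjusted p = 0.192 with an estimated correlation, 0.073 without background correction and 0.052 without NSC replicate 2). Imprinted genes rose in 9 and fell in 2 of 17, with the growth factor gene Igf2 at 6.54 ± 0.19 (0.0399, adjusted p = 0.233 with an estimated correlation, 0.061 without background correction and 0.086 without NSC replicate 3).

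Between ESC NPC and NSC 6265 genes changed (limma), 3032 higher and 3233 lower, and with median scaling 2095 higher and 4386 lower. Among the largest rises were the growth factor gene Mdk (7.33 ± 0.25), the hormone precursor Trh (at least 78.5-fold) and Shh, a ventral patterning signal (at least 66.8-fold), and among the falls the lipase gene Mgll (-5.78 ± 0.14). Genes at least 4-fold higher on the ESC array than in iNSC, 777 in all, were higher in ESC NPC in 615 cases and lower in 31 (camera p = 4.99e-35, and p = 0.000207 with an estimated correlation). Thus 79.2% were higher, against 23.8% of the other genes. The set was chosen for low levels in iNSC, which correlated with NSC at 0.945, so part of this rise is built in. Median scaling in place of quantile normalization moved the median of all genes by -0.17 here, by 0.15 in iNSC against ESC NPC, by 0.21 in iNSC against MEF, by -0.76 in iNSC in vivo against iNSC and by -0.84 in NSC in vivo against NSC. Every change is therefore relative to the distribution that quantile normalization gave all arrays.

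Set against ESC NPC, iNSC showed the neural stem list higher in 14 of 16 genes and lower in none, with Olig2 at least 3.71-fold higher, Notch1 at 3.26 ± 0.18 and Egfr at 3.21 ± 0.14 (list adjusted p = 8.82e-05). Pluripotency genes were lower in 17 of 18 and epithelial genes in 11 of 12, Lin28a by at least 23.4-fold and Esrp1, a splicing regulator of epithelia, by at least 27.4-fold (2.49e-13 and 3.14e-07). These calls held with an estimated correlation, at adjusted p = 0.0356, 0.00573 and 0.0175. Hox genes were higher in 15 and lower in 1 of 20, Hoxa7 by 4.53 ± 0.12 (4.18e-05, adjusted p = 0.0512 with an estimated correlation). Astrocyte genes were higher in 12 and lower in 2 of 21, Aldoc by 4.86 ± 0.15 and Gfap by at least 11.5-fold (0.00539, adjusted p = 0.227 with an estimated correlation).

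Cell cycle genes were lower in iNSC than in ESC NPC in 21 and higher in 1 of 25, or 22 and 1 adjusted over the list alone, with Mcm3 lower by at least 7.08-fold (0.000128, adjusted p = 0.646 with an estimated correlation). Cholesterol genes were lower in 13 and higher in 1 of 17, with Lss at -2.40 ± 0.13 (0.00283, adjusted p = 0.426 with an estimated correlation). Fibroblast genes were lower in 14 and higher in 3 of 26 (0.00836, adjusted p = 0.218 with an estimated correlation) and imprinted genes lower in 11 of 17, or 12 adjusted over the list alone (0.000426, adjusted p = 0.0785 with an estimated correlation). Ependymal genes were lower in 6 of 10 (0.00839, adjusted p = 0.109 with an estimated correlation), as were midbrain and hindbrain genes in 8 of 12, with 1 higher (0.00406, adjusted p = 0.085 with an estimated correlation). In total 6593 genes changed (limma), 3435 higher and 3158 lower in iNSC, and 4365 and 2290 with median scaling. The mitochondrial gene Chchd10 was at least 128-fold lower in iNSC, and Cntn1, an axonal adhesion gene, rose by 5.08 ± 0.26.

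The comparison of iNSC with the MEF array asked how the induced cells differ from fibroblasts. All 26 measured fibroblast genes were lower in iNSC: Dcn by at least 447-fold, the collagen gene Col1a1 by at least 86.1-fold and Thy1 by at least 102-fold (3 against 1 array; list adjusted p = 1.53e-16, adjusted p = 0.0111 with an estimated correlation). Neural stem genes rose in 12 and fell in 1 of 16, Sox21 by 4.50 ± 0.23, Slc1a3, a glutamate transporter gene, by 2.93 ± 0.19 and Sox2 by 1.95 ± 0.23 (0.0048, adjusted p = 0.085 with an estimated correlation). Microglia genes fell in 11 of 20, Lyz2 by at least 11.6-fold and Cd14 by at least 18.2-fold, as the MEF array detected them (4.2e-05, adjusted p = 0.0291 with an estimated correlation). The MEF array also detected 96 of 99 genes abundant in NSC and at background on ESC, a set chosen after seeing the data, at a median of -2.44 log2 in MEF minus NSC. Xist stood at 8.22 and Eif2s3y at 4.18 on MEF, against 4.24 and 8.95 in iNSC, so this MEF array differed from iNSC in its sex-linked transcripts.

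Immediate early genes fell in iNSC against MEF in 12 and rose in 1 of 20, Ier3 by at least 135-fold (0.00162, adjusted p = 0.34 with an estimated correlation), and interferon genes fell in 11 and rose in 2 of 22, Ifitm3 by 6.92 on the log2 scale (0.00616, adjusted p = 0.574 with an estimated correlation). Cholesterol genes fell in 9 and rose in 1 of 17 (0.0145, adjusted p = 0.542 with an estimated correlation), imprinted genes fell in 11 and rose in 1 of 17 (0.000238, adjusted p = 0.0696 with an estimated correlation), and endothelial genes fell in 7 and rose in 1 of 18 (0.028, adjusted p = 0.155 with an estimated correlation). Hox genes did not shift as a list, 4 higher and 9 lower of 20 (0.354), with Hoxd9 at 2.26 ± 0.14 and Hoxc6 at -1.73 ± 0.13. In total 5443 genes changed (limma), 3053 higher and 2390 lower, and 3978 and 2038 with median scaling. Beyond the listed genes the protease gene Mmp3 fell by at least 407-fold and the chemokine gene Ccl7 by at least 319.9-fold, while Nrarp, a Notch target, rose by 5.43 ± 0.23.

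ESC NPC against the ESC array asked how these progenitors differ from embryonic stem cells. Hprt and Thumpd1 were undetected in ESC NPC and at least 95.3-fold and 25.3-fold higher on ESC. The differences can therefore not be ascribed to differentiation alone. The MEF and ESC values also carry more decimals than the rest, and whether these arrays were handled apart is unknown. Pluripotency genes fell in 15 and rose in 3 of 18, with Dppa3 at -4.25 ± 0.12, Esrrb at -4.20 ± 0.17 and Nanog at -2.75 ± 0.26 (3 against 1 array; list adjusted p = 1.43e-05, adjusted p = 0.0272 with an estimated correlation). Neural stem genes rose in 9 and fell in 1 of 16, Slc1a3 by at least 93.5-fold and Fabp7, a radial glia lipid carrier, by at least 6.50-fold (0.000631, adjusted p = 0.0512 with an estimated correlation). Fibroblast genes rose in 15 and fell in 1 of 26, or 16 and 1 adjusted over the list alone, Dcn by at least 22.3-fold (1.09e-05, adjusted p = 0.0643 with an estimated correlation). Astrocyte genes rose in 10 and fell in 2 of 21 (0.0399, adjusted p = 0.377 with an estimated correlation and 0.080 without background correction). Ependymal genes rose in 7 and fell in 1 of 10, as did 7 and 1 of 12 midbrain and hindbrain genes, each with adjusted p = 0.109 with an estimated correlation after 0.00839 and 0.00836. Hox genes rose in 8 of 20 (0.00836, adjusted p = 0.163 with an estimated correlation). Altogether 4883 genes changed (limma), 2420 higher and 2463 lower, and 1884 and 2883 with median scaling, and Shh rose by at least 60.9-fold.

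NSC in vivo was compared with NSC and iNSC in vivo with iNSC, to see what differed in the brain. The labels do not tie NSC in vivo to the cultured NSC. Y-linked Eif2s3y was detected in NSC in vivo and not in NSC. The Xist probe that stands for the gene was detected only in NSC of these, but a second one stood at 7.12 in NSC in vivo and 7.10 in NSC. On both arrays all 20 microglia and macrophage genes were higher. Laptm5, a lysosomal membrane gene, was at least 588-fold higher in NSC in vivo and at least 556-fold higher in iNSC in vivo, and Lyz2 at least 111-fold and 469.6-fold. Laptm5 was also detected on ESC (12.3) and in ESC NPC (8.94), so it is not particular to microglia here. The list had adjusted p of 2.5e-12 and 6.52e-13, and adjusted p = 0.00573 with an estimated correlation in both. Endothelial genes were higher in 16 of 18 in NSC in vivo, Vwf by at least 256-fold, and in 15 of 18 in iNSC in vivo, Vwf by at least 45.3-fold (7.82e-08 and 8.39e-06, or adjusted p = 0.0152 and 0.026 with an estimated correlation). On signals before normalization 13 of 18 endothelial genes were higher for NSC, with a median of 1.59 log2, but 10 of 18 for iNSC, with a median of 0.23. Interferon genes were higher in 21 of 22 on both arrays, with Psmb9 at 5.02 ± 0.21 and 6.65 ± 0.21 (6.65e-06 and 4.86e-07, but adjusted p = 0.311 and 0.245 with an estimated correlation). Some of these rises rest on background. Undetected were 5 of the 22 interferon genes in NSC in vivo and 4 in iNSC in vivo. In NSC in vivo 1 microglia gene and 2 endothelial genes were undetected, and in iNSC in vivo 6 endothelial genes. The haemoglobin gene Hba-a1, undetected in every culture, was at least 287-fold higher in NSC in vivo and at least 17.6-fold higher in iNSC in vivo.

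Neural stem genes were lower in 14 of 16 and higher in none on both in vivo arrays, which were also the dimmest. This fall was not separated from a loss of RNA or from a dilution by RNA of other cells. Medians of 59 ribosomal protein genes were -1.96 in NSC in vivo and -1.53 in iNSC in vivo. With undetected genes at the lowest detected level of their array they were -1.68 and -1.03. Each array left 11 of the 16 neural stem genes undetected, and at that level 12 were still lower in NSC in vivo and 14 in iNSC in vivo. Sox2 was lower by at least 3.46-fold in NSC in vivo and 3.32-fold in iNSC in vivo, Fabp7 by at least 5.79-fold and 4.52-fold, and Egfr by at least 10.9-fold in NSC in vivo and by 3.17 ± 0.20 log2 in iNSC in vivo (list adjusted p = 0.00034 and 0.000191, or adjusted p = 0.0473 and 0.0418 with an estimated correlation). Myelin genes stood among the rises in both: Mobp was at least 73.1-fold higher in NSC in vivo and at least 29.7-fold in iNSC in vivo, and the mature oligodendrocyte list rose in 7 and fell in 2 of 16 on each (0.155 and 0.158). Neuron genes rose in 10 and fell in 7 of 19 in NSC in vivo and rose in 10 and fell in 3 in iNSC in vivo, the synaptic gene Syn1 by 3.79 ± 0.28 and 3.74 ± 0.28 (0.391 and 0.221). Astrocyte genes rose in 4 and fell in 9 of 21 in NSC in vivo and rose in 6 and fell in 9 in iNSC in vivo (0.262 and 0.407). Immediate early and dissociation genes rose in 18 of 20 in NSC in vivo and in 11 of 20, with 1 lower, in iNSC in vivo, Atf3 by at least 32.7-fold and 30.1-fold (0.000231 and 0.00616, but adjusted p = 0.245 and 0.406 with an estimated correlation). Each in vivo array left 3 of these 20 genes undetected.

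Cholesterol genes fell in 12 and rose in 3 of 17 in NSC in vivo (0.0247, adjusted p = 0.576 with an estimated correlation), and in iNSC in vivo 8 fell and 5 rose (0.443). Of the 12 in NSC in vivo 10 were undetected there, and at the lowest detected level of the array 5 were still lower by at least 2-fold. Ependymal genes rose in 7 and fell in 1 of 10 in iNSC in vivo, Ttr, a choroid plexus carrier gene, by at least 39.2-fold (0.037, adjusted p = 0.187 with an estimated correlation). In NSC in vivo 6 rose and 2 fell (0.0563). Of the 10 ependymal genes 5 were undetected in NSC in vivo and 6 in iNSC in vivo. Hox genes fell in 12 and rose in 3 of 20 in iNSC in vivo, Hoxa7 by 3.93 on the log2 scale (0.0349, adjusted p = 0.233 with an estimated correlation). Of these 12 Hox genes 7 were undetected in vivo, and at that level 8 were still lower, 6 of them by at least 2-fold. That Hox call ended at 0.114 with median scaling, 0.054 with the deposited values and 0.056 without a filter. These falls, like those of other lists in vivo, were not separated from a loss of RNA or from a dilution by RNA of other cells. The largest falls included ribosomal protein genes, Rps7 by at least 104-fold in NSC in vivo and 93.3-fold in iNSC in vivo. The test called 7425 genes in each comparison (limma), 3700 higher and 3725 lower in NSC in vivo and 3668 and 3757 in iNSC in vivo. With median scaling these were 1624 and 5933, and 1532 and 5800. Among genes detected on every array compared, a setting chosen after seeing the data, 3359 and 3206 passed.

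The in vivo differences of NSC and iNSC correlated across genes at r = 0.845 and rho = 0.828, with no array shared, and at r = 0.881 over the 4859 genes detected on both in vivo arrays. Genes higher on both numbered 2862, where independent calls would give 1242, and 2960 were lower on both. Independence is not a fair reference here, because the 2 cultures correlated at 0.945 and both in vivo arrays were dim. Similar cultures and a shared low signal can give a high r and overlap. These values therefore do not separate a shared response from those. A test of the difference between the in vivo effects called 3037 genes (limma), 1476 and 1561 in either direction, or 1794 with median scaling. Among the 4067 genes detected on every array compared, a setting chosen after seeing the data, it called 750, 318 and 432 in either direction. Between the in vivo arrays themselves, with no replicate and no test, 552 genes stood at least 4-fold apart, 301 higher in iNSC in vivo and 251 in NSC in vivo. That number was 131 without background correction, 273 with median scaling and 43 among genes detected on both of them and on every NSC and iNSC array, the same added setting.

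Genes with the largest difference toward iNSC in vivo included Cd70, Fpr2 and Arg1, genes of immune cells, at least 12.4-fold, 33.2-fold and 9.05-fold, and toward NSC in vivo Gkn3 (at least 8.83-fold) and the actin gene Acta2 (-4.22). Of 87 alternatives for the genes named for this pair 43 moved by more than the spread between clones. The medians of the interferon and microglia lists lay toward iNSC in vivo at percentile 100 of 10000 random lists matched on size and level. Microglia members went both ways. Among the 4 with the largest differences, Lyz2 (2.12), Tyrobp (1.67) and Cd14 (1.47) lay toward iNSC in vivo and P2ry12 (-1.51) toward NSC in vivo. Endothelial and mature oligodendrocyte genes lay toward NSC in vivo at percentile 0. Cholesterol, cell cycle, Hox, ependymal and neuron genes also ranked near either end, but many of their members were undetected, so those ranks are not interpreted. Undetected were 17 of 25 cell cycle genes on each array, and on NSC in vivo 20 of 20 Hox, 10 of 17 cholesterol, 5 of 10 ependymal and 9 of 19 neuron genes.

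**Figure D3:**
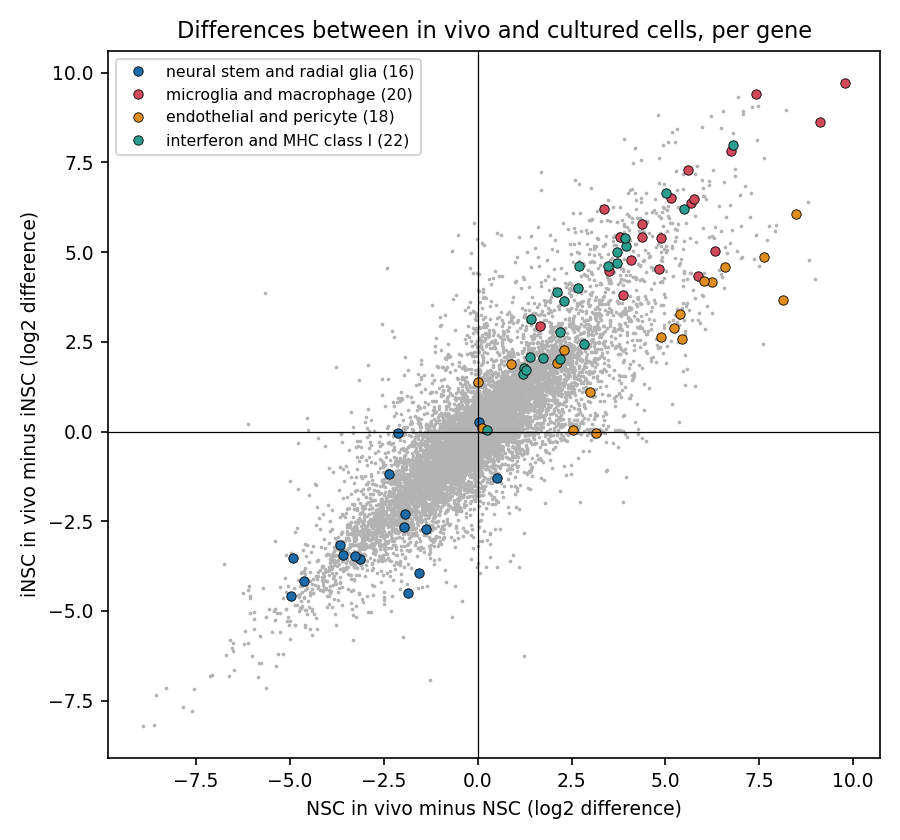
Log2 difference in vivo minus culture for each gene tested, NSC on the horizontal axis and iNSC on the vertical axis, with members of fixed lists coloured. The points follow a rising line (r = 0.845), with all 20 microglia genes above 0 on both axes.

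Over 22 lists and 7 comparisons 58 of 154 list tests passed with the preset correlation, and 16 also with an estimated correlation, each of which is named above with its value. A list's median, mean and test differed in sign for neural stem, fibroblast, astrocyte and microglia genes in iNSC against NSC, immediate early and sex-linked genes in ESC NPC against NSC, and interferon genes in iNSC against ESC NPC. They also differed for pluripotency and both oligodendrocyte lists in iNSC against MEF, and mature oligodendrocyte and sex-linked genes in ESC NPC against ESC. In the in vivo comparisons this held for pluripotency, forebrain, sex-linked and epithelial genes with iNSC, and hypoxia, epithelial and conversion factor genes with NSC. None of these lists passed its test.

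**Figure D4:**
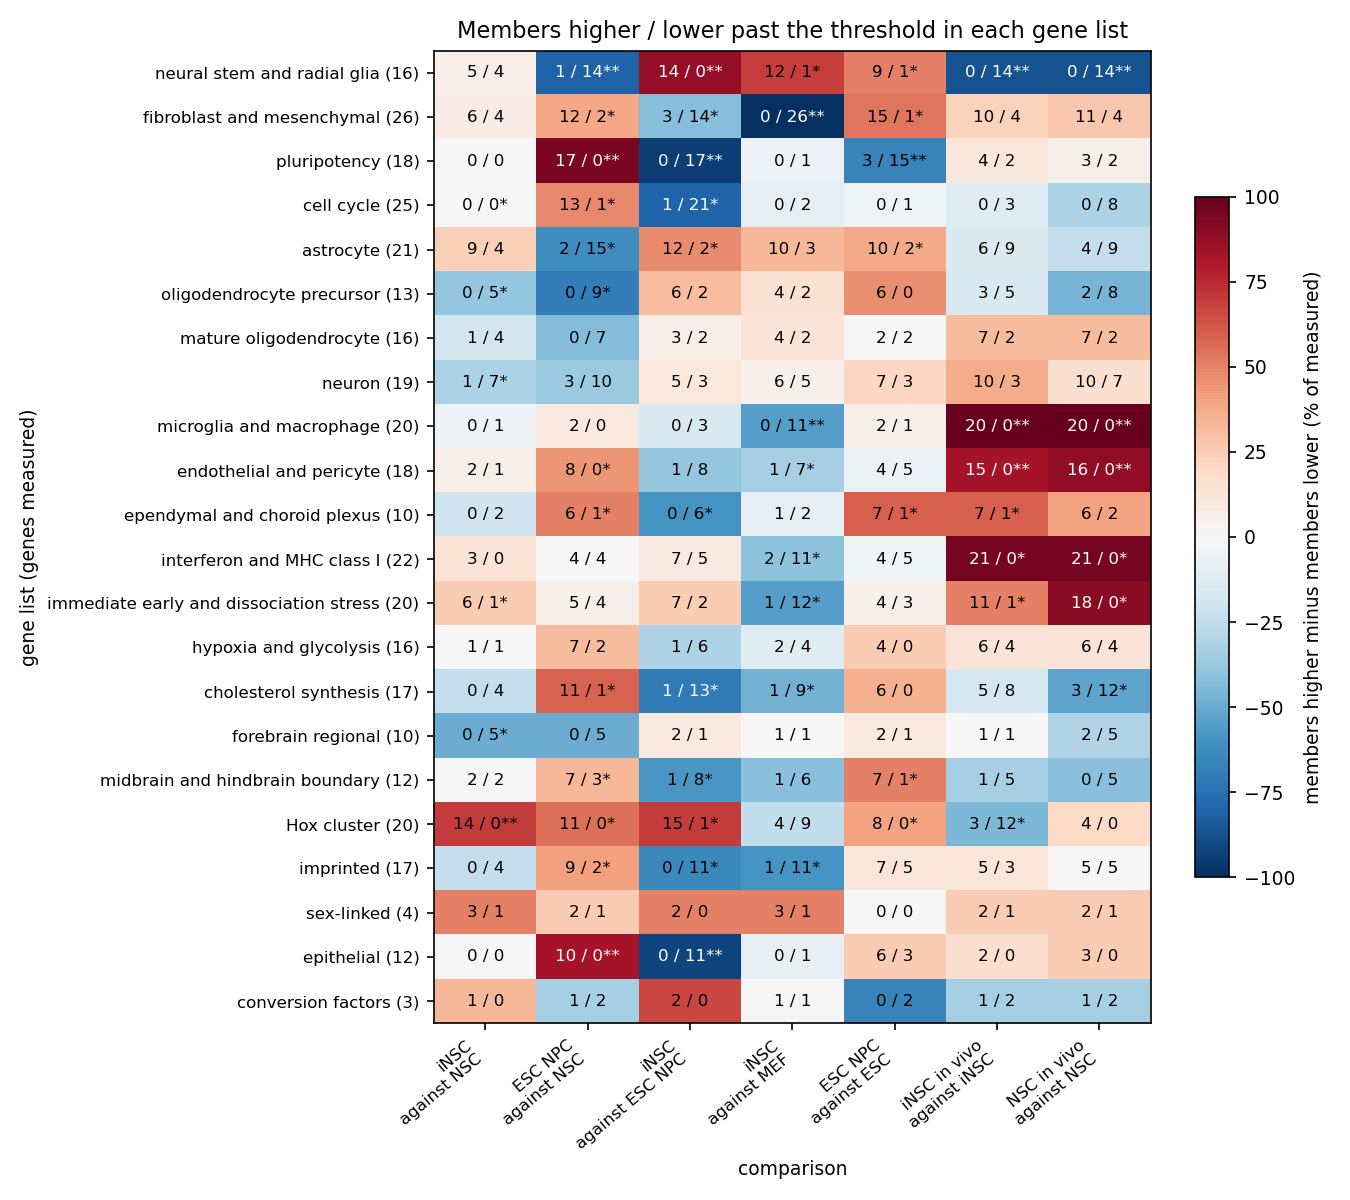
Number of members higher / lower past the threshold for each gene list (vertical axis, with the number measured) in each comparison (horizontal axis), coloured by members higher minus members lower in percent. A star marks a list test past the threshold with the preset correlation and a pair of stars with both correlations, as for the 14 Hox genes higher in iNSC than in NSC.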

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

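All tests of causes below were chosen only after the results were seen, except the splits of arrays and the test of the difference between the in vivo effects. That test compared iNSC in vivo minus iNSC with NSC in vivo minus NSC and called 3037 genes (limma), or 750 of the 4067 detected on every array compared. Among the markers Eif2s3y, undetected in NSC, stood at -3.46 (adjusted p = 4.7e-05), or -2.87 with NSC at the lowest detected level, Thy1, undetected in iNSC, at 2.03 (0.00019), or 1.55 at that level, and Klf4 at -2.08 (0.0019). Y-linked Eif2s3y stood at 4.30 in NSC and 8.54 in NSC in vivo, against 8.95 in iNSC and 9.73 in iNSC in vivo. Its value can reflect RNA of cells other than the cultured NSC, and does not show that the in vivo effects differ. Xist (4.57, 6.7e-07), Kdm5d (-1.67, 0.002) and Nes (-2.64, 0.024) were undetected on both in vivo arrays, so their values rest on background there and do not show that the effects differ. A second Xist probe, detected on NSC in vivo, stood at 7.12 there and 7.10 in NSC. Nes did not pass without background correction (-1.29, 0.152), with median scaling (-1.34, 0.278) or with the mean of probes (-1.46, 0.105). Gfap, undetected on NSC in vivo, stood at 1.78 (0.031), but at -0.38 at that level, and did not pass without background correction (0.49, 0.371), with median scaling (0.16, 0.920) or without iNSC replicate 3 (0.0605). Each in vivo group is a single array, so this test rests on the spread of the cultured clones.

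All 20 microglia genes were higher on both in vivo arrays, though 1 of them was undetected on NSC in vivo. Normalization as the whole cause is argued against, since on signals before normalization the list's median was still 1.43 log2 higher for NSC, with 19 of 20 members higher, and 2.16 for iNSC with 20 of 20. RNA from cells other than the cultured NSC may have entered the NSC in vivo sample, since Y-linked Eif2s3y, undetected in NSC, was higher there by 4.24, at least 12.5-fold. For iNSC in vivo, 37 of 74 genes undetected in iNSC but detected in all NSC, ESC NPC and ESC arrays were detected. NSC in vivo detected 34 of the same 74, though cultured NSC hold all of them. Other cells or a change of the transplanted cells could both give the 37. The part of each cannot be told apart with 1 array.

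Probes of one gene moved apart in vivo: 28.0% of 1665 genes with several probes had probes more than 2 log2 apart in iNSC in vivo minus iNSC, against 2.58% in MEF minus iNSC. Probes undetected in vivo can part by background alone, and with these at the lowest detected level 8.65% were shown to part, against 2.46%. Normalization as the whole cause is argued against by 9.25% on signals before normalization, or 3.96% at that level, against 1.20% and 1.14% for MEF. Fewer intact transcripts in the in vivo RNA may account for this. Other transcript forms stay open, because 361 genes parted on both arrays where 130 would by chance, or 107 and 13.2 at that level, which loss by probe position could also give.

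Hox genes were higher in iNSC than in NSC. Fibroblasts left among the iNSC are argued against: 60 other genes abundant on MEF had a median of -5.75 in iNSC minus MEF, with 41 undetected on all iNSC arrays, or -5.18 with these at the lowest detected level, while 4 abundant Hox genes had a median of -0.09. Whether a Hox pattern kept from the fibroblasts remains stays open. Levels of 20 Hox genes in iNSC and on MEF ranked alike (rho = 0.792), but probe affinity could also give this, and ESC NPC, which do not come from fibroblasts, gave 0.635 with MEF.

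The 6 arrays of each comparison of 3 against 3 clones make 10 splits, too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many genes. The real values were 2150 for iNSC against NSC, 6265 for ESC NPC against NSC and 6593 for iNSC against ESC NPC, and the highest other split gave 0 in each. Every other split puts arrays of both cell types in the same group, so their difference enters the spread and lowers the count. These splits therefore cannot decide on chance.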

How the results depend on the processing

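The settings without the in vivo arrays, with genes detected on every array compared and with the block in list tests were chosen after seeing the data. Of 10148 alternatives for named genes 9966 kept a call with its direction or stayed uncalled, whatever the sign. Another 132 lost the call, 45 gained it and 5 reversed, meaning a turned sign with a call in the main or the alternative setting. The genes named for the in vivo pair are counted apart: 44 of 87 alternatives stayed within the spread between clones and 43 moved. The reversals were Eif2s3y (-0.89) and Uty (-0.55) in iNSC in vivo and Neu4 (-0.0593) and Cldn7 (-0.0120) in NSC in vivo with median scaling, and Xist (0.0306) in NSC in vivo with the deposited values, where another Xist probe stands for the gene. Of 1584 list alternatives 1486 kept their call, and 42 of 60 losses came with an estimated correlation, under which 16 list shifts held, and 5 with the block and an estimated correlation together. Of 38 gains 17 came with median scaling. With an estimated correlation, the 642 MEF genes in iNSC against NSC had a median of 0.0657 and no longer passed camera, whereas they passed with every clone left out in turn. Genes with differing in vivo effects numbered 1794 with median scaling and 750 when detected on every array, and the in vivo pair gave 131 without background correction, 273 with median scaling and 43 when detected on every array. With detection on every array 3206 genes passed for iNSC in vivo and 3359 for NSC in vivo. The correlation of the in vivo differences was 0.854 without background correction, 0.875 with median scaling, 0.825 with deposited values, 0.841 without a filter, 0.852 with detection on at least 3 arrays, 0.842 with the mean of probes and 0.859 with detection on every array. The similarity of iNSC and NSC was 0.952 without background correction and 0.930 with deposited values. The cause of these shifts was not tested.

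Leaving out 1 clone at a time gave 1693 to 2255 genes for iNSC against NSC, 5629 to 6314 for ESC NPC against NSC, 5973 to 6255 for iNSC against ESC NPC, 5038 to 5319 for iNSC against MEF and 4320 to 4337 for ESC NPC against ESC. It gave 7131 to 7324 for iNSC in vivo, 7147 to 7482 for NSC in vivo, 2702 to 3318 for the difference between in vivo effects, 58 to 61 list shifts and a correlation of 0.841 to 0.846. The median of the MEF genes ranged from 0.05 to 0.10 and that of the ESC genes from 1.24 to 1.43. Without the in vivo arrays 2127 genes changed in iNSC against NSC. A fit with the replicate block gave 2187, 6344 and 6649 genes in the comparisons of 3 against 3. In iNSC against NSC Ccne1 (-0.53, adjusted p = 0.030), Rrm2 (-1.62, adjusted p = 0.024) and Aqp1 (0.46, adjusted p = 0.044) gained the call, and the block changed no other call of a named gene or list under either correlation. With the block 163 MEF genes were higher and 69 lower, with a median of 0.0657, and the set passed camera with the preset correlation but not with an estimated one. Same-numbered clones correlated at -0.0420 to -0.00918 in ESC NPC against NSC and at 0.0362 to 0.115 in iNSC against ESC NPC. These gave less sign of a pairing than iNSC and NSC, where it is not established either. A fit of only the 2 groups gave 1455, 6225 and 6890. A block by chip was not run, because column names give no barcode. The low signal over background on the in vivo arrays limits what can be said of genes undetected there.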

Other observations

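The tests here were chosen after the data were seen. The MEF array carried transcripts abundant in neural stem cells, mostly at lower levels. Of 99 genes abundant in NSC and at background on ESC, it detected 96, with a median of -2.44 log2 in MEF minus NSC, and of 107 such genes in iNSC it detected 103. Of 61 genes abundant on ESC and at background in NSC and iNSC it detected 25.

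Hprt was undetected in ESC NPC and stood at 11.4 on ESC, at least 95.3-fold higher. Thumpd1, an RNA-binding gene, was at least 7.52-fold lower in iNSC than in NSC. It was also undetected on MEF and in ESC NPC, and was detected on ESC and on both in vivo arrays. Brat1 was undetected in NSC and detected on every other array.

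The 59 ribosomal protein genes had differences with an SD of 2.23 in iNSC in vivo minus iNSC and 2.26 in NSC in vivo minus NSC, against 0.705 in iNSC minus MEF, with undetected genes at the lowest detected level of their array. Loss of part of the RNA may contribute, as 28.0% of genes with several probes had probes that parted in iNSC in vivo, 8.65% at that level. Measuring RNA integrity in samples from brain beside cultures would test this.

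The MEF array held Xist and lacked Eif2s3y, while iNSC held Eif2s3y and lacked Xist. Fibroblasts from the embryos whose cells were converted would test whether a Hox pattern is retained.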
